A study of Homo sapiens with 35 samples.

How the data were processed

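Total RNA from 35 biologically distinct samples of uninvolved mammary tissue, labelled with the disease state breast cancer, was measured on Agilent 1-colour expression arrays. Per the labels, the tissue was frozen in liquid nitrogen, RNA was extracted with Trizol and labelled with Cy3. The labels give 1 group, no control group and no genotype, so the data were described across samples and no groups of patients were compared. Each sample was hybridised once, so p-values measure the spread between these samples, which holds both technical and biological differences.

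The scanner files hold, per the file headers, spot intensities from Agilent Feature Extraction. Versions 10.7.3.1 and 10.7.1.1 were used, the second in scan batch 6 alone. Per the file headers, the processed intensity was background-subtracted and detrended across the array by that software, with surrogate values for dim spots, and was not normalized between arrays. The mean spot intensity and the local background median intensity were taken from the same deposited files. The authors also deposited a table of log2 values, made with limma per the submitters' processing notes, which give no version and no further step. Its column medians lay between 7.86 and 7.98, so the columns were on 1 scale, but the authors' background correction, centring method and any batch correction were not given in the sources used here. Higher values were brighter, since 34 of 35 columns followed their own scanner file best after centring each probe, with r between 0.36 and 0.872. For 1 sample the deposited column did not follow its file (r -0.134), and the number in its title and the scan day in its label also differed from the file. That sample was kept and was left out as an alternative.

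Each array had 43376 non-control spots of 41000 probes. The main values were log2 of the processed intensity minus the array's 75th percentile over non-control spots. Spots marked as outliers by the scanner software (0.106% to 1.28% of spots per array) were left out, no spot was saturated, and spots of 1 probe were averaged. Array designs came in 3 versions and 2 genome builds, and probe coordinates are those of the newest design, in hg19. Gene names were taken from a table of the GRCh38.p14 annotation, used for names only, through accessions (26222 probes), symbols (1646) or synonyms (466). The other 12666 probes were left unnamed and counted as features of their own. A gene was represented by its brightest probe among those well above background on 18 or more arrays, which left 22580 features, 15106 genes and 7474 unnamed probes. For 5687 genes several probes passed this filter, and they often disagreed. The median over these genes of the lowest correlation with the chosen probe was 0.167, and 3555 genes had a probe below 0.3.

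The precision of the values was limited by the number of arrays and by their signal. The 75th percentile intensity ranged from 144 to 4322 (median 741), and 55.4% to 90.4% of spots per array were well above background. Samples were scanned in 8 batches on 25 slides, with the batch taken from the labels, and on 2 scanners per the file headers. The 6 arrays of scan batch 6 were the dimmest, with a 75th percentile of 144 to 369 against 436 to 4322 on the other 29. The median coefficient of variation of repeated spots, per the file headers, was 34.7% to 54.0% on these 6 and 7.13% to 16.0% on the others. On 4 of these 6 arrays 7158 to 10971 probes shared 1 minimum value, which is a bound. All 6 had dim areas, with 22.7% of 132 tiles dim on the array with the lowest signal and up to 20.5% on the other 5, and no other array did.

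Two-sided permutation tests with 100000 resamples gave p-values for Pearson's r and Spearman's rho, and 1e-05 is the smallest p they can give. Every r was repeated without the 2 samples farthest from the median of the first-named measure, on residuals after scan batch means, and within scan batches 3, 6 and 7 (9, 6 and 6 samples), since other batches held under 6. A list score was the mean over a list's members of each gene's standardised values. For a pair of lists, shared members were left out, and MRPS30 and ESR1 were left out of all scores. Slopes on MRPS30 and on ESR1 were fitted for each feature with lmFit and eBayes with a trend (limma 3.58.1 in R 4.3.3), with scan batch as a fixed term, and are log2 units of the feature per log2 unit of the regressor. Scan batches were compared with limma's F test over the 6 batches of 3 or more samples (32 samples). P-values were adjusted by Benjamini and Hochberg within each family at 0.05. Gene lists were tested with camera, with a preset correlation of 0.01 and again with an estimated correlation. The median SD of each list was ranked among 10000 random lists of the same size matched on mean signal in 20 bins. Mixture models were fitted with mclust 6.1.1, and figures were drawn with matplotlib.

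The 23 gene lists, written from general knowledge of cell types and processes, the tests, the rule for naming genes and most other choices to be tested were fixed before the data were examined. The small subunit list of the mitochondrial ribosome holds MRPS36, whose current symbol is KGD4. Its place in that ribosome is uncertain, and counts of small subunit genes include it. The text names every 5p12 gene with a probe and the 12 largest positive and 12 largest negative moderated t among genes passing in each fit. It also names the 20 largest SDs, the 8 largest F and up to 4 members per list. A few genes that these rules would name were withheld for evaluation and left out of the text. For privacy, XIST, Y-linked, HLA, immunoglobulin and T cell receptor genes and genes with common deletions were not named. The other choices tested were normexp on the mean and background intensities with an offset of 50, quantile normalization, the deposited table, stricter and no filters on dim probes, the mean of a gene's probes, slide as a random block, and covariates for array quality (the 75th percentile and the share well above background) or for cell type scores (adipocyte, epithelial, fibroblast matrix). Fits without scan batch 6, without the array with the lowest 75th percentile signal, without floor values and with scan batch from the file headers were added after seeing the data.

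Functions were tested on simulated data with the real means, spreads and assignment of samples to batches. Errors were drawn independently for each gene and batch shifts at random, so these rates do not cover the correlation between real genes. Among 200 of 22580 features given a slope of 1 on the measured ESR1 values, 75.5% were called and 5.62% of calls were false. With a slope of 0.5, 20.5% were called and 4.65% of calls were false. For scan batches, 55.0% of 200 features given batch shifts with an SD of 1 were called and 8.33% of calls were false, and with an SD of 0.5 these were 11.5% and 14.8%, above the 5% aimed at. The adipocyte list given a slope of 0.5 was called by camera at adjusted p = 3.59e-11, with 0 of the other lists called. Members of real lists were correlated (estimated in the ESR1 fit at 0.66 for epithelial and 0.41 for adipocyte genes). The simulation therefore cannot show how often camera calls real lists falsely. A correlation of 0.6 was recovered in 98.5% of 200 runs, and 7.5% of 200 unrelated pairs had p under 0.05. A list with doubled SDs lay above 100% of random lists.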

Results

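The 35 arrays measured gene expression in mammary tissue that was not part of the tumour, labelled with the disease state breast cancer. The series title concerns the breast cancer risk locus at 5p12, on the short arm of chromosome 5, and MRPS30, which codes for a protein of the mitochondrial ribosome. The data allow 3 kinds of question, namely what signal the probes of the 5p12 genes gave, how much each gene varied between samples, and which genes varied together with MRPS30 or with the estrogen receptor gene ESR1. No genotypes or tumours were analysed here. All levels are log2 signal relative to the array's 75th percentile. They depend on the probe as well as on the transcript, so they do not rank genes by expression.

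The list called 5p12 here was written wider than that band, and genes of 5p12 below means its members. Of these, EMB, PARP8 and ISL1 lie on the long arm. Probes of these genes are at 49692285, 50138626 and 50689606 on chromosome 5 in hg19, for PARP8 that of an unused probe. Among the listed genes SELENOP, which codes for a secreted selenium transport protein, had the brightest probe at 5.67 ± 0.44 (SD, n = 35). GHR, the growth hormone receptor, averaged 2.01 ± 2.01, and HMGCS1, an enzyme of cholesterol synthesis, 1.10 ± 1.34. MRPS30 averaged -1.42 ± 0.89 and was well above background on 34 of 35 arrays. On the array with the lowest 75th percentile signal its value of -6.02 equalled a minimum that 10971 probes shared there, so it is a bound. Without that array MRPS30 was at -1.28 ± 0.40 (n = 34) and lay between -1.97 and -0.59. Its probe lies on chromosome 5 at 44812022 to 44812081 in hg19, and whether this is coding sequence or UTR was not annotated in the files used here. A second MRPS30 probe was dimmer (-5.48 ± 0.84, well above background on 23 arrays) and did not follow the first (r 0.173 across 35 arrays).

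ZNF131 averaged 0.75 ± 1.23, EMB 0.00 ± 0.73, NNT, the mitochondrial transhydrogenase, -1.02 ± 1.52, TMEM267 -1.49 ± 0.74 and the epithelial chemokine CCL28 -1.96 ± 2.37. PARP8 averaged -2.14 ± 1.31, and the growth factor FGF10 -4.15 ± 0.86, well above background on 31 arrays. NIM1K averaged -4.25 ± 0.75 and C5orf34 -5.17 ± 0.62. The PAIP1 probe (1.34 ± 1.48) has coordinates on chromosome 17 in the files, so its level is uncertain as a measure of the 5p12 gene. The ISL1 probe was well above background on 2 arrays and was not tested. Values of NNT, CCL28 and C5orf34 on 1 array each and of PARP8 on 2 arrays also equalled the array's minimum and are bounds, and without them the 4 SDs were 1.08, 2.30, 0.51 and 0.56. Leaving out scan batch 6 reduced the SD of GHR to 0.93, of NNT to 0.93, of PARP8 to 0.54 and of ZNF131 to 0.44, while that of CCL28 stayed at 2.28 (n = 29).

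**Figure D1:**
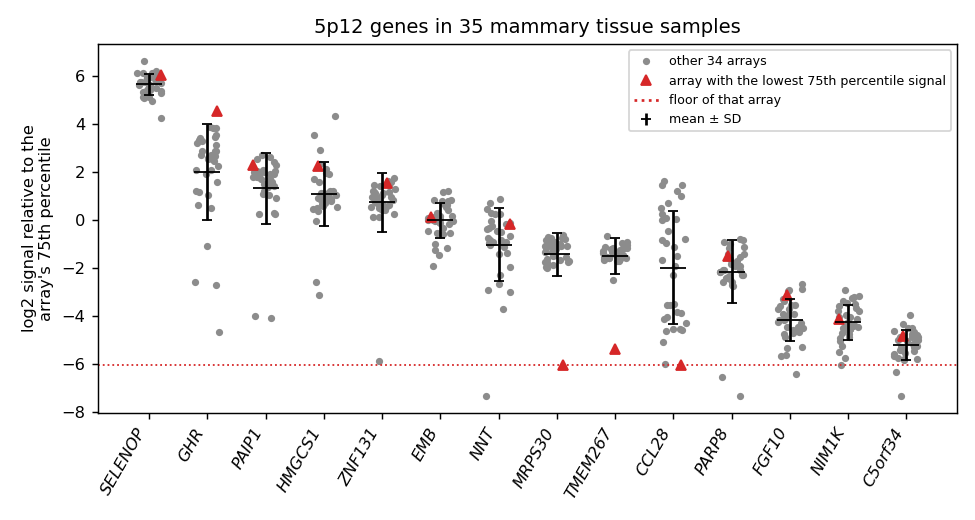
Log2 signal of 14 genes of the 5p12 list on the y axis in 35 samples, of which EMB and PARP8 lie on the long arm. Black bars are the mean ± SD, and the red triangle is the array with the lowest 75th percentile signal. The dotted line is the minimum of that array, -6.02, at which its MRPS30 value lies, while the other 34 MRPS30 values lie between -1.97 and -0.59.

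The 20 genes with the largest SD between samples included several secreted proteins and keratins, and 7 of the 20 belonged to the cell type lists. PIP, a protein secreted by exocrine glands, had the largest SD (4.69 around a mean of 1.80), followed by MUCL1 (4.64), the mammaglobin gene SCGB2A2 (4.63) and the related secretoglobins SCGB1D1 (4.22), SCGB1D2 (4.12) and SCGB2A1 (3.66). PIGR, which carries immunoglobulins across epithelium, had an SD of 4.17, and the keratin genes KRT15, KRT6B and KRT17 had SDs of 4.11, 4.08 and 3.8. The others of the 20 largest were FDCSP (4.07), the oxytocin receptor gene OXTR (3.89), COL17A1 (3.86), the E-cadherin gene CDH1 (3.82), PLEKHS1 (3.81), UGT2B7 (3.75), the estrogen-induced gene TFF1 (3.71), VTCN1 (3.70), RIPK4 (3.61) and ROPN1 (3.58). The median SD of all features was 0.93, and 0.64 without scan batch 6. With probes well above background on all arrays only 1 of these 20 genes remained among the 20 largest, since genes near background on some arrays were then not ranked.

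Lists of epithelial and fat cell markers varied more than matched random lists. The median SD was 2.53 over 15 luminal secretory genes, 2.40 over 15 myoepithelial genes, 2.32 over 19 epithelial genes, 1.87 over 24 genes of hormone responsive luminal cells and 1.54 over 23 adipocyte genes, each above all 10000 random lists. With probes well above background on all arrays the hormone responsive list fell to percentile 81.3 (median SD 0.89 over 10 genes), while the other 4 stayed above 95. Within the epithelial list CDH1, KRT7 (SD 3.25), KRT19 (3.10) and EPCAM (3.09) varied most, and within the adipocyte list PLIN4 (1.96), LEP (1.90), CIDEC (1.89) and PCK1 (1.76). Skeletal muscle genes (median SD 1.55) and immediate early genes (1.37) also lay above all random lists. The latter were led by FOSB (2.44), EGR2 (2.13), EGR1 (1.96) and FOS (1.92). With probes well above background on all arrays immediate early genes stayed at 99.9, and the skeletal muscle list was not ranked. Red cell genes (percentile 99.95), B and plasma cell genes (99.8), macrophage genes (96.6) and fibroblast matrix genes (95.2) lay above 95% of random lists. Fibroblast matrix and macrophage genes fell below 95 in some other settings, the former to 83.0 and the latter to 73.1 with probes well above background on all arrays. B and plasma cell genes fell to 93.0 with no filter on dim probes. The 14 genes of 5p12 lay at percentile 86.2, but at 28.9 without floor values, 46.96 without scan batch 6 and 37.6 with the mean of a gene's probes. It was 93.7 after quantile normalization, 94.2 on scan batch residuals and 99.5 with no filter on dim probes (16 genes), so this rank depended on the choices made. The cytosolic ribosome (64.3), pericyte and smooth muscle (63.1), endothelial (52.9), T and NK cell (46.7), proliferation (74.0) and interferon response (85.5) lists lay lower. The mitochondrial ribosome lists (12.8 for the small and 12.0 for the large subunit), oxidative phosphorylation (13.99), mast cell (20.1) and heat shock genes (8.37) varied less than the median random list. Several of these lower ranks depended on scan batch 6 or on the values used. Without it the cytosolic ribosome list lay at percentile 0.62, pericyte and smooth muscle genes at 99.4, endothelial genes at 92.2, T and NK cell genes at 96.6, oxidative phosphorylation at 78.3, mast cell genes at 74.2 (78.2 with normexp values) and heat shock genes at 54.8. In the deposited table mast cell (96.2), T and NK cell (97.6), pericyte and smooth muscle (99.6) and interferon response genes (95.5) lay above 95% of random lists. The small and large subunit lists of the mitochondrial ribosome stayed low without scan batch 6, at 8.30 and 4.10. Percentiles describe these samples and are not p-values.

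Samples with high scores for epithelial genes had low scores for adipocyte genes. The 2 scores correlated at r -0.82 (rho -0.88, both with adjusted p = 6e-05, n = 35), and the adipocyte score also fell with that of hormone responsive luminal genes (r -0.83, rho -0.82). Endothelial genes followed adipocyte genes (r 0.73, rho 0.64) and ran against epithelial genes (r -0.75, rho -0.71). The score of B and plasma cell genes rose with the epithelial score (r 0.66, rho 0.74), and macrophage genes rose with fibroblast matrix genes (r 0.58, rho 0.59). Of 78 pairs of the 13 cell type lists, 31 passed at adjusted p under 0.05, and p-values behind r of -0.82 and -0.83 were the smallest that permutations can give. Within scan batches 3, 6 and 7, epithelial and adipocyte scores correlated at -0.78, -0.95 and -0.92 (9, 6 and 6 samples), and hormone responsive and adipocyte scores at -0.85, -0.95 and -0.88. Adipocyte and endothelial scores correlated there at 0.75, 0.80 and 0.86, epithelial and endothelial scores at -0.84, -0.92 and -0.68, epithelial and B and plasma cell scores at 0.91, 0.19 and 0.92, and fibroblast and macrophage scores at -0.07, 0.72 and 0.93. Thus the last relation did not hold in scan batch 3 and the plasma cell relation was weak in scan batch 6. Without the 2 farthest samples the 6 pooled values were -0.81, -0.80, 0.68, -0.67, 0.63 and 0.47 in the order epithelial and adipocyte, hormone responsive and adipocyte, adipocyte and endothelial, epithelial and endothelial, epithelial and plasma cell, fibroblast and macrophage. The largest gap between neighbouring samples was 9.22% to 21.97% of a score's range. Mixture models split the hormone responsive, luminal secretory, epithelial, adipocyte and endothelial scores into 2 components and the myoepithelial score into 3, and left the other scores as 1. Without the array with the lowest 75th percentile signal the hormone responsive score was not split. The relations were looked at within components for the epithelial score alone, where 29 and 6 samples were parted. There epithelial and adipocyte scores correlated at -0.84 within the 29 and at 0.01 within the 6, epithelial and endothelial scores at -0.76 and 0.49, and epithelial and B and plasma cell scores at 0.53 and -0.10. These values were not tested.

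**Figure D2:**
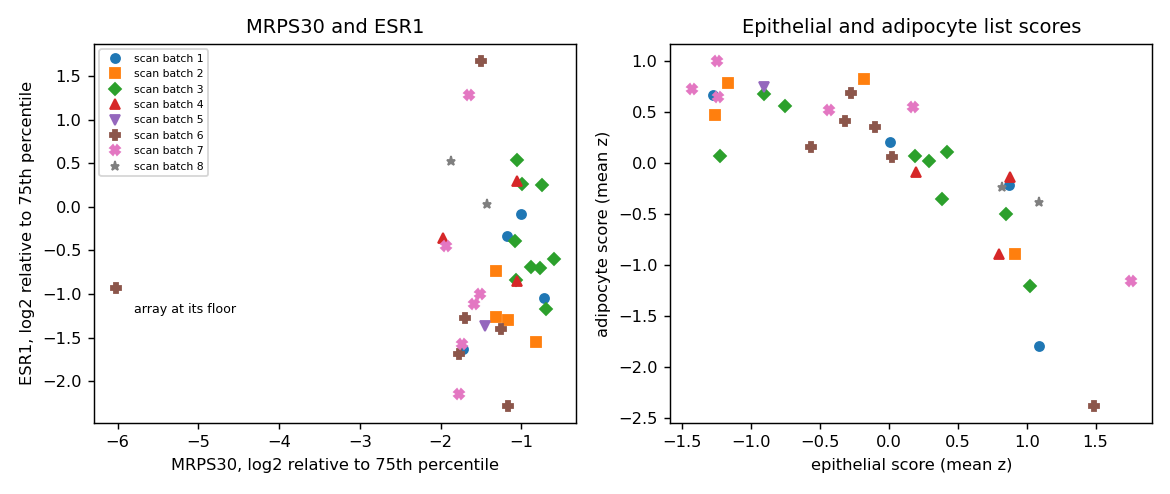
Left, log2 signal of ESR1 on the y axis against MRPS30 on the x axis in 35 samples, with 1 array at its minimum of -6.02 for MRPS30. Right, the adipocyte score against the epithelial score (mean standardised values), r -0.82, with symbols for the 8 scan batches.

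No correlation of MRPS30 with ESR1, with other genes of 5p12 or with any list score passed by permutation across the 35 samples. The correlation with ESR1 was r 0.06 (permutation p = 0.716, a family of 1) and rho 0.17 (p = 0.331), 0.07 without the 2 farthest samples, 0.05 (p = 0.796) without the array at its minimum and -0.03 on scan batch residuals. Within scan batches 3, 6 and 7 it was -0.36, -0.04 and 0.09 (9, 6 and 6 samples). With the mean of each gene's probes r was -0.39 (p = 0.0317), where the dimmer second probes enter with equal weight. Of 13 other 5p12 genes, 0 passed by permutation of r or rho, and 2 had an unadjusted p under 0.05 for r. These were TMEM267 (r 0.83, p = 0.0091, adjusted p = 0.0633, rho 0.16) and CCL28 (r 0.37, p = 0.00974, adjusted p = 0.0633, rho 0.29). For rho 2 others had an unadjusted p under 0.05, PARP8 (rho -0.44, p = 0.0092, adjusted p = 0.12) and C5orf34 (rho 0.37, p = 0.0305, adjusted p = 0.198). The TMEM267 value rested on the array at its minimum, since r was 0.09 without it and 0.05 without the 2 farthest samples, and within scan batches 3, 6 and 7 it was -0.23, 0.94 and 0.11. CCL28 also stood at the minimum of that array. Without it the CCL28 value was r 0.24 (permutation p = 0.173, adjusted p = 0.538, n = 34). Of 22 gene lists, 0 passed, and 1 had an unadjusted p under 0.05 for r, that of pericytes and smooth muscle (r -0.34, p = 0.0416, adjusted p = 0.915, rho -0.17, and -0.01 without the 2 farthest samples). For rho the red cell (rho -0.40, p = 0.0177) and skeletal muscle (rho -0.39, p = 0.021) lists were under 0.05, with adjusted p = 0.231 for both. For the small and large mitochondrial ribosome lists, to which MRPS30 belongs by function, r was 0.13 and 0.09 (adjusted p = 0.973 and 0.988), and -0.24 and -0.18 without the array at its minimum (adjusted p = 0.536 and 0.83, n = 34). Without that array 0 of the lists passed either, and the pericyte value was -0.08. MRPS30 did rise with the array's log2 75th percentile signal (r 0.54, p = 0.00019, adjusted p = 0.00057 over 3 measures, rho 0.50, 0.53 without the 2 farthest samples and 0.47 without the array at its minimum). Within scan batches 3, 6 and 7 that relation was -0.71, 0.77 and 0.75, so its direction was not shared. On scan batch residuals r was 0.32 (permutation adjusted p = 0.034). It was 0.25 there without the array at its minimum (adjusted p = 0.386), so the relation did not pass. The other 2 measures passed as well, the coefficient of variation of repeated spots (r -0.57, adjusted p = 0.00313, rho -0.44) and the share of spots well above background (r 0.43, adjusted p = 0.0169, rho 0.13). Without the array at its minimum their r was -0.27 and 0.08 (adjusted p = 0.175 and 0.635).

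Across all features the slope on MRPS30 passed for 5670 of 22579, 4005 positive and 1665 negative, and this count rested on 1 array. Without the array with the lowest 75th percentile signal limma called 0 features, with 1635 at an unadjusted p under 0.05. Leaving out each of the other 34 samples in turn gave at least 5020. With all arrays, the largest positive t belonged to GLUD1, glutamate dehydrogenase (slope 1.63 ± 0.11 SE), the transfer RNA synthetase genes IARS1 (1.49 ± 0.10) and YARS2 (1.04 ± 0.07), the DNA repair kinase gene PRKDC (1.18 ± 0.08), the chromatin gene CBX3 (1.90 ± 0.13) and the topoisomerase gene TOP2B (1.86 ± 0.13). The others were ZSCAN18 (1.43), POTEM (2.13), RBM15B (1.10), DNTTIP1 (1.52), RBM39 (1.73) and RPL31 (2.59), with adjusted p from 1.49e-11 to 1.92e-11 for all 12 and slopes of 0.13 to 0.55 without that array. The largest negative t belonged to NDRG4 (-1.06), CSRP2 (-1.02), CDNF (-0.70), LUZP2 (-0.94), THAP7-AS1 (-0.80), TBC1D17 (-0.45), AIMP1 (-0.36), GARRE1 (-1.15), SLFN12 (-0.73), GHR (-1.26), ABRAXAS1 (-0.44) and UBQLNL (-0.72). Without that array the GHR slope was 0.04, and the others stayed negative, between -1.32 (THAP7-AS1) and -0.07 (ABRAXAS1). Those of CSRP2 (-1.30), THAP7-AS1, UBQLNL (-1.27) and TBC1D17 (-0.52) were larger in size than with all arrays, and the rest were smaller. Their SEs were larger, for CSRP2 0.59 against 0.19. The signs of the called features were 70.6% positive in the main values and 87.6% in the deposited table, where 556 were called, while normexp values gave 0 calls.

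The lists showed the same dependence. Of 29 small subunit genes of the mitochondrial ribosome 9 had positive slopes, 5 negative and 15 did not pass (9, 6 adjusted over the list alone), and of 47 large subunit genes 14 were positive, 4 negative and 29 did not pass (14, 6 adjusted over the list alone). The largest t were those of MRPS18B (slope 0.99), MRPS31 (1.00), MRPS16 (1.45) and MRPS28 (1.02), and of MRPL39 (1.12), MRPL33 (1.18), MRPL36 (1.17) and MRPL3 (0.94). Without the array at its minimum 0 of the small and 0 of the large subunit genes passed. Of 34 cytosolic ribosome genes 12 were positive and 4 negative, and of 33 oxidative phosphorylation genes 4 and 4. In the 5p12 list TMEM267 (0.76) was positive and GHR, PAIP1 (-0.82) and PARP8 (-0.67) were negative with all arrays. Camera called 0 of 23 lists, with 1 at an unadjusted p under 0.05 (oxidative phosphorylation, p = 0.0486). Without that array it called 4 lists, all lower with higher MRPS30, namely macrophage (adjusted p = 3.79e-06), T and NK cell (0.000175), mast cell (0.0136) and red cell genes (0.0375). With an estimated correlation the adjusted p of these 4 was 0.428, 0.428, 0.428 and 0.983, and 0 of their members passed over all features.

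**Figure D3:**
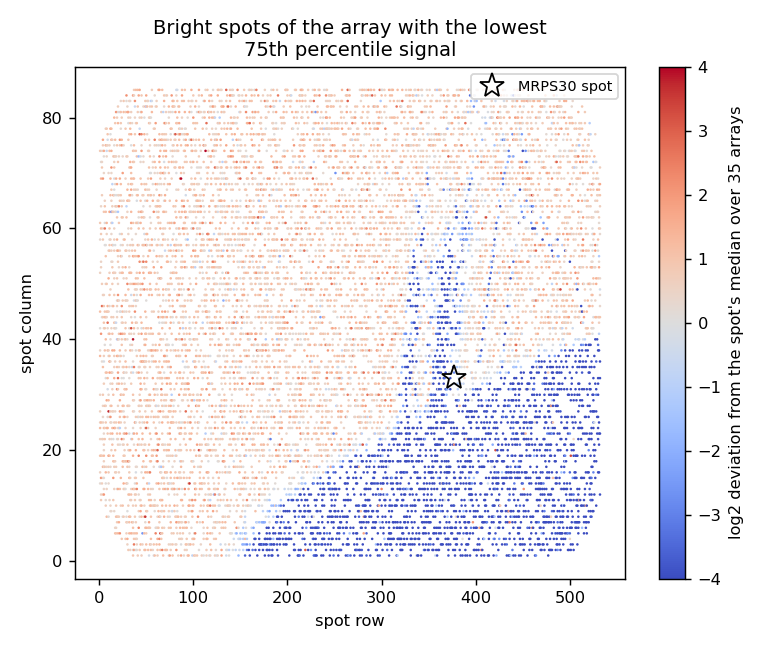
Positions of 10782 bright spots (median log2 signal above the 75th percentile) on the array with the lowest 75th percentile signal, by spot row (x axis) and column (y axis), coloured by log2 deviation from each spot's median over 35 arrays. Spots near the MRPS30 spot (star) deviated by a median of -3.41, against 0.53 for all bright spots of this array.

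Genes of epithelial cells, both luminal and myoepithelial, rose with ESR1, and genes of fat cells fell. The slope on ESR1 passed for 4131 of 22579 features (2120 positive, of which 1366 genes, and 2011 negative, of which 1588 genes). MUC1, an epithelial mucin, had the largest t (slope 2.12 ± 0.22 SE, adjusted p = 2.97e-06), followed by the myoglobin gene MB (1.94 ± 0.22), ATP2C2 (2.39), PCP2 (1.53), SULT2B1 (1.61), AGR3 (2.65), HPN (1.66), SEC14L2 (2.10), AP1M2 (1.89), TTC39A (1.37), SYT6 (1.80) and CYP4Z2P (2.39). On the negative side stood ITGA7 (-1.05 ± 0.13), LVRN (-1.48), the adipokine gene ADIPOQ (-1.43 ± 0.19, adjusted p = 1.82e-05), the fatty acid carrier gene CD36 (-1.36), SLC66A1LP (-1.05), ALDH2 (-1.18), CDO1 (-1.12), SNN (-0.73), CCDC85A (-1.02), CFL2 (-0.76) and RDH5 (-1.34). ESR1 itself averaged -0.68 ± 0.89 (n = 35), was well above background on all 35 arrays, and was measured by a probe on chromosome 6 at 152423908 to 152423967 in hg19, whose place in the gene was not annotated in the files used here. A second ESR1 probe, well above background on 28 arrays, followed it weakly (r 0.197). The share of positive slopes among the calls was 51.3%, against 39.6% after quantile normalization and 61.9% in the deposited table. It was 33.3% with probes well above background on all arrays. Without the 2 samples with the most extreme ESR1 596 features were called, 539 positive and 57 negative (90.4% positive). Most of the 2011 negative calls thus depended on these 2 samples. Leaving out 1 sample in turn gave 2072 to 5814 calls. With adipocyte, epithelial and fibroblast matrix scores as covariates limma called 0, with 1318 at an unadjusted p under 0.05.

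By lists, 19 of 19 epithelial genes rose with ESR1, for example PKP3 (slope 1.69), KRT18 (2.02) and PROM2 (1.70). Of 24 genes of hormone responsive luminal cells 18 rose, 1 fell and 5 did not pass, with AGR3, PRLR (1.82), AGR2 (2.70) and MLPH (1.88) leading. The 1 that fell was BCL2 (-0.41), named after its value was seen. Of 15 luminal secretory genes 12 rose and 3 did not pass, led by LCN2 (1.44), SLPI (1.52), WFDC2 (1.84) and SOX10 (1.55), and of 15 myoepithelial genes 12 rose and 3 did not pass, led by TRIM29 (2.34), ITGB4 (0.74), KRT14 (1.67) and SFN (1.05). Of 23 adipocyte genes 21 fell and 2 did not pass, among them ADIPOQ, CD36, PPARG (-1.11) and RBP4 (-1.33). Adjusted over the list alone, 19 epithelial, 19 hormone responsive, 13 luminal secretory and 13 myoepithelial genes rose, and 21 adipocyte, 1 hormone responsive and 1 luminal secretory gene fell. Camera called these 5 lists at adjusted p = 3.57e-20, 1.6e-13, 8.22e-07, 2.77e-08 and 5.52e-19 in the order epithelial, hormone responsive, secretory, myoepithelial, adipocyte. With an estimated correlation the hormone responsive and adipocyte lists kept their call (adjusted p = 0.0426 for both), while epithelial genes had an adjusted p = 0.0594 and the secretory and myoepithelial lists 0.21. The hormone responsive and adipocyte calls were lost as well without the array with the lowest 75th percentile signal (adjusted p = 0.102 and 0.11 with an estimated correlation). The same held without scan batch 6 (0.145 and 0.214). With cell type scores as covariates the secretory and myoepithelial lists turned negative (median slopes -0.56 and -0.53). Their adjusted p with an estimated correlation was then 0.225 and 0.22.

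Camera called 9 further lists, each lost with an estimated correlation (adjusted p between 0.21 and 0.576). Oxidative phosphorylation genes were lower with higher ESR1 (12 of 33 fell, 17 adjusted over the list alone, adjusted p = 8.22e-07), led by NDUFS4 (-0.34), SDHB (-0.38), COX7B (-0.50) and NDUFB6 (-0.65). Of the mitochondrial ribosome 8 of 47 large and 3 of 29 small subunit genes fell and 0 rose (adjusted p = 0.00116 and 0.0261), with MRPL15 (-0.31), MRPL40 (-0.54), MRPL1 (-0.29) and MRPL35 (-0.28) leading the large subunit and MRPS11 (-0.31), MRPS22 (-0.63) and MRPS18C (-0.25) in the small one. Of 16 endothelial genes 5 fell (ROBO4 -0.59, ERG -0.55, VWF -0.40, CDH5 -0.49 and MMRN2 -0.29, the last named after its value was seen, adjusted p = 0.00287). Of 16 macrophage genes 4 fell (MSR1 -0.71, VSIG4 -0.57, C1QB -0.45, TYROBP -0.40, adjusted p = 0.0038), of 23 interferon response genes 3 (OASL -0.72, IFIT3 -0.53, ISG15 -0.77, adjusted p = 0.00401), and of 8 red cell genes 3 (HBA2 -1.13, ALAS2 -0.93, HBA1 -0.74, adjusted p = 0.01). Of 24 fibroblast matrix genes 3 fell (FBN1 -1.01, COL5A2 -0.73, ASPN -0.56, adjusted p = 0.0291). Of 10 B and plasma cell genes 3 rose (TNFRSF17 1.21, JCHAIN 1.52, MZB1 1.21, adjusted p = 0.0361). Adjusted over the list alone, 8 large and 3 small subunit, 7 endothelial, 4 macrophage, 3 interferon, 5 red cell and 3 fibroblast genes fell and 4 plasma cell genes rose. Counts in these lists depended on 1 array. Without the array with the lowest 75th percentile signal 16 large and 10 small subunit genes fell and 1 of each rose, and 19 oxidative phosphorylation, 9 endothelial, 7 macrophage, 8 interferon and 5 fibroblast genes fell while 1 fibroblast gene rose. With cell type scores as covariates the endothelial list turned positive (median slope 0.31, adjusted p = 0.0134 with an estimated correlation). Red cell genes depended on scan batch 6, since without it 0 of 8 passed, their median slope moved from -0.63 to -0.12 and camera did not call them (adjusted p = 0.673).

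The remaining lists were not called by camera with ESR1 as the regressor. In the 5p12 list CCL28 rose (1.5 ± 0.36, adjusted p = 0.00412) and SELENOP (-0.34) and EMB (-0.40) fell, and 11 of 14 did not pass. In the skeletal muscle list MB and TNNI2 (0.96) rose while TNNT3 (-0.89) and MYH1 (-1.15) fell, and among pericyte and smooth muscle genes ACTG2 rose (1.63) while MCAM (-0.88), CSPG4 (-1.03) and RGS5 (-0.44) fell. The proliferation genes BIRC5 (1.41) and RRM2 (0.85), the mast cell list's KIT (0.88), also a luminal progenitor gene, HSPA1A (0.89) and CD3E (0.48) rose, KLF2 (-0.72) and GZMB (-0.47) fell, and 0 of 34 cytosolic ribosome genes passed.

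**Figure D4:**
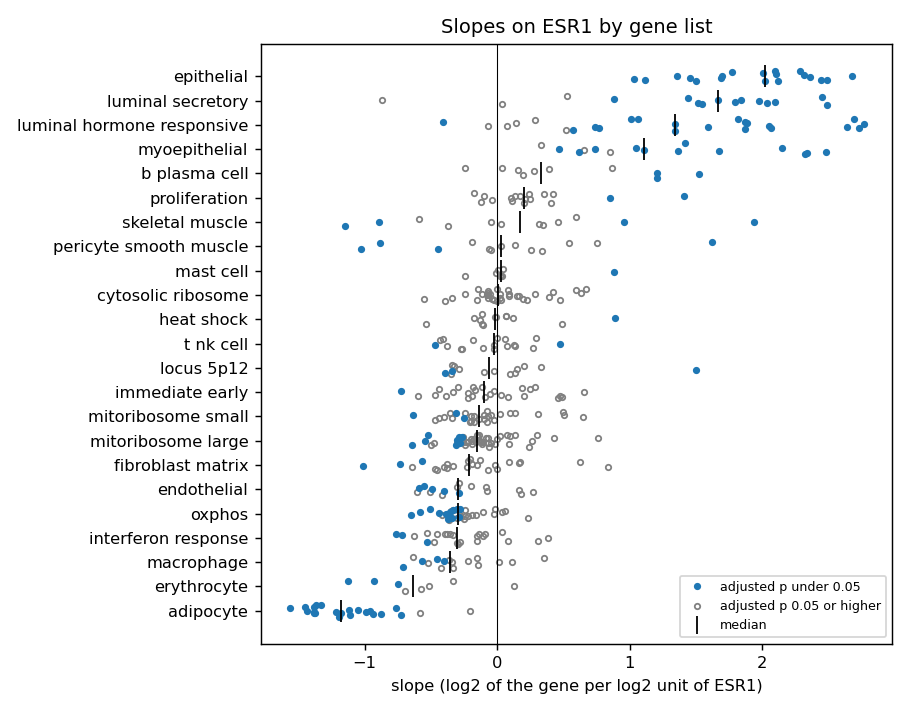
Slope on ESR1 (x axis, log2 of the gene per log2 unit of ESR1) for the members of 23 gene lists, filled where the adjusted p is under 0.05, with list medians as bars. The median slope is 2.02 for the epithelial list and -1.18 for the adipocyte list.

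Scan batches differed for 6092 of 22580 features (27.0%, limma's F test, 32 samples in 6 batches). The largest F belonged to STAG3L1, whose mean was 3.98 in scan batch 6 and between 0.81 and 1.12 in the other 5 batches (adjusted p = 1.14e-08). The transcribed copies TCP1P3 (-3.40), AGAP7P (-3.12) and NACA4P (-4.17) and the gene BTN2A1 (-6.08) had their lowest mean in scan batch 7. The histone gene H2AC4 was highest in scan batch 6 (0.51), and LCE2D ranged from -0.61 in scan batch 7 to 4.68 in scan batch 3. Several of these have near-identical copies, so their probes may not measure that gene alone. Of the gene lists, 11 of 29 small subunit genes of the mitochondrial ribosome differed (37.9%, 15 adjusted over the list alone), against 27.0% of all features. For 11 of 47 large subunit genes (23.4%) and 5 of 24 hormone responsive genes (20.8%) the share was below that of all features. Of 19 epithelial, 23 adipocyte and 26 immediate early genes 0 differed. ESR1 did not pass (adjusted p = 0.687). MRPS30 did not pass with all arrays (0.192), which rested on the array at its minimum. Without that array it passed (adjusted p = 0.00731, 31 samples), with means from -0.87 in scan batch 3 to -1.70 in scan batch 7, and 8462 features differed in all. With normexp values 11362 features differed between scan batches, and in the deposited values only 23 did.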

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

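Levels, lists and fits were repeated with other choices of background correction, scaling, probes, samples and covariates. All choices fixed beforehand were run. Fits without scan batch 6, without the array with the lowest 75th percentile signal, without floor values and with scan batch from the file headers were chosen after seeing the data. Unless said otherwise the cause of a change was not tested.

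The number of correlated pairs of cell type lists was stable, at 28 to 36 of 78 in all settings against 31. The 4131 features related to ESR1 were 3153 to 5814 in most settings and fewer in those below. MRPS30 calls depended on 1 array.

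With normexp values 13 of the 20 most variable genes were shared, 0 features were related to MRPS30 (5670 in the main values), camera called 13 lists in that fit (0 in the main values), and 11362 features differed between scan batches (6092). The median slope of all features on MRPS30 moved to 0.35 from -0.10. Slopes on MRPS30 turned positive for CDNF (0.72), LUZP2 (0.13), THAP7-AS1 (0.35), SLFN12 (0.55), ABRAXAS1 (0.17) and UBQLNL (0.23), with adjusted p from 0.155 to 0.864. List shifts in that fit changed sign for the small (-1.52) and large (-1.45) mitochondrial ribosome, cytosolic ribosome (-1.36), macrophage (-2.16), red cell (-1.28), heat shock (-1.23) and proliferation (1.17) lists. These are mean t-values of a list minus those of the other features, each with adjusted p under 0.05 by camera at the preset correlation. With an estimated correlation all 13 calls were lost (adjusted p from 0.223 to 0.6), and 0 members passed over all features.

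Quantile normalization gave a correlation of MRPS30 and ESR1 of -0.0014 (0.06 in the main values). The deposited table shared 12 of the 20 most variable genes, and gave 556 features related to MRPS30, 1537 related to ESR1 and 23 differing between scan batches.

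With probes well above background on all arrays 1 of the 20 most variable genes and 7 lists above 95% of random lists (11 in the main values) remained. There 1694 features were related to MRPS30 and 2081 to ESR1, 3972 differed between scan batches, and camera called 9 lists for ESR1 (14). Slopes of the remaining probes of ZSCAN18 (-0.10) and RPL31 (-0.30) on MRPS30 changed sign. With no filter on dim probes 12157 features differed between scan batches.

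With the mean of a gene's probes MRPS30 averaged -3.45 (-1.42), correlated with ESR1 at -0.39 (p = 0.0317) and with 1 other 5p12 gene at adjusted p under 0.05, and 2781 features were related to it. With each gene's other probe 201 features were related to MRPS30. In that fit slopes changed sign for TOP2B (-0.082), NDRG4 (0.0883), CSRP2 (0.23), CDNF (0.12), LUZP2 (0.15), AIMP1 (0.0025), GHR (0.29) and ABRAXAS1 (0.0476).

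Scan batch residuals gave a correlation of MRPS30 and ESR1 of -0.0264. With array quality as covariates it was -0.0549, and MRPS30 was then related to 1 other 5p12 gene and 2 list scores. With cell type scores as covariates MRPS30 was related to 2 other 5p12 genes.

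Without floor values and without the lowest-signal array 0 features were related to MRPS30, the GHR slope was 0.0402, and camera called 4 lists. Of these the macrophage (-1.60 in both), mast cell (-1.31 and -1.29) and red cell (-1.14 and -1.13) lists had changed sign. With an estimated correlation and without the lowest-signal array these calls were lost (adjusted p from 0.428 to 0.983). Without the 2 farthest samples and with a rank-transformed regressor 0 features were called as well.

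Without scan batch 6 MRPS30 was related to 1 list score and 0 features, with slopes of RPL31 (-0.0279), CDNF (0.11) and GHR (0.25) changing sign. Camera then called 8 lists, and those that changed sign were the small mitochondrial ribosome (-0.58), cytosolic ribosome (-0.98), macrophage (-1.02), mast cell (-1.17), red cell (-1.74) and immediate early (0.89) lists. With an estimated correlation all 8 calls were lost (adjusted p from 0.548 to 0.844), and 0 members passed over all features.

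For ESR1, slide as a random block in place of scan batch gave 2387 features. Leaving out the 2 farthest samples gave 596, of which 57 were negative. With cell type scores as covariates 0 features were called and camera called 8 lists. With an estimated correlation the endothelial list alone kept its call (adjusted p = 0.0134), and the other 7 had an adjusted p from 0.0562 to 0.743. The shift changed sign for the small mitochondrial ribosome (0.0158), oxidative phosphorylation (0.14), luminal secretory (-1.16), myoepithelial (-1.22), adipocyte (0.0682), fibroblast matrix (0.10), endothelial (1.25), B and plasma cell (-2.11), red cell (0.18), proliferation (-1.15) and interferon response (0.53) lists. Since 2 of these lists are themselves covariates, their values there describe what the covariates left over.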

Other observations

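Genes of mitochondrial energy metabolism varied with the score of fat cell genes. The oxidative phosphorylation score rose with the adipocyte score (r 0.83, rho 0.85, adjusted p = 6e-05, n = 35, with p at the smallest value permutations can give) and fell with the epithelial score (r -0.71, rho -0.72). Scores of the large and small subunits of the mitochondrial ribosome, the complex that contains MRPS30, also rose with the adipocyte score (r 0.66 and 0.59, adjusted p = 6e-05 and 0.00054). Within scan batches 3, 6 and 7 oxidative phosphorylation and adipocyte scores correlated at 0.90, 0.77 and 0.79 (9, 6 and 6 samples), and at 0.79 over all batches without the 2 farthest samples. MRPS30 itself did not follow the adipocyte score (r -0.10, adjusted p = 0.973).

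Proliferation genes rose with the epithelial score (r 0.45, rho 0.50, adjusted p = 0.0118), within scan batches 3, 6 and 7 at 0.71, -0.11 and 0.79. Interferon response genes fell with it (r -0.48, rho -0.53, adjusted p = 0.00735), within these batches at -0.45, -0.91 and -0.57, and the values without the 2 farthest samples were 0.42 and -0.34. Skeletal muscle, immediate early, heat shock and cytosolic ribosome genes did not pass with either score (smallest adjusted p = 0.461 for r and 0.158 for rho). These 18 relations were chosen after seeing the data.

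The fit without 1 array, the dim area and the 100 arrangements of values were tested after the MRPS30 result was seen. For the 5670 features related to MRPS30, limma called 0 without the array with the lowest 75th percentile signal, where MRPS30 stood at the array's minimum. On that array 99 bright spots within 10 rows and columns of the MRPS30 spot lay -3.41 log2 from their medians, against 0.53 for all its bright spots and -0.24 to 0.38 near MRPS30 on the other 34 arrays. Spots around features with positive slopes lay -4.84 from their medians, against 0.74 around the others, so a dim area on 1 array, shared by MRPS30 and those features, fits the result. Of 100 arrangements of the MRPS30 values over the samples, the real one included, 2 gave as many features (highest other count 5671), but each keeps the minimum as an outlier, so they say nothing for or against chance, and no biological explanation was tested.

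The cell type and array quality fits were set before the ESR1 result was seen. The rules for judging them and the 100 arrangements of values came after it. The median slope of the 4131 features related to ESR1, taken in the direction of its first sign, was 0.63 (median SE 0.16) and became 0.11 (median SE 0.27) with adipocyte, epithelial and fibroblast matrix scores as covariates. The sign was kept for 65.7% of these features. The makeup of the samples thus fits the drop in slope. However, scan batch and these scores explained 0.787 of the variance of ESR1, which leaves little to test within a given makeup. With array quality as covariates 4276 features were called, so these whole-array measures do not explain the ESR1 result. With the same covariates 4673 features were related to MRPS30, and 4516 of these were among the 5670 with the same sign. These covariates thus do not capture a dim area on 1 array. This test therefore cannot exclude local faults. Without scan batch 6, which held all arrays with dim areas, 4463 features were called. Of these, 2807 were among the 4131 with the same sign, so dim areas were not the whole cause. That fit was added after seeing the data. Of 100 arrangements 1, the real one, gave as many features, and the highest other count was 3244. No biological explanation was tested.

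The fits below were set beforehand for scan batches, except the fit without scan batch 6 and the 100 arrangements of values. The rules for judging them were written after the result was seen. Between scan batches 6092 features differed, and 7528 without scan batch 6, so its dim arrays were not the whole cause. With adipocyte, epithelial and fibroblast matrix scores as covariates 7021 differed, so these scores alone do not account for the result. Other cell types were not covariates, and covariates can also lower the residual spread, so this count cannot exclude makeup as a part of it. Only 23 features differed in the deposited values, but whether the authors corrected for batch is unknown, and a correction would lower this count for technical and donor differences alike. Of 100 arrangements 1, the real one, gave as many features, and the highest other count was 396. Batches also held different donors, and biological differences between them were not tested. An effect of the scanner was not tested either.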
